A study of Mus musculus with 7 samples.

How the data were processed

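Bone marrow of female mice was profiled by strand-specific mRNA sequencing, with 3 libraries labelled as Aim2 knock-out (KO) and 4 as wild type (WT). RNA was taken up on a column kit and the libraries were sequenced on the DNBSEQ platform, per the labels' protocols. Groups and sample numbers were taken from the sample titles and the genotype label. Read quality was checked with FastQC 0.11.9 and transcripts were quantified with Salmon 1.7.0, per the submitters' processing notes, which also name the mouse build GRCm38.p6 and DESeq2. The release of the transcript annotation and the options given to Salmon were not given in the sources used here.

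The deposited files hold, for each of 116546 transcripts, its length, its effective length, an estimated read count that need not be whole, and a TPM value, a relative abundance corrected for transcript length. In each library 37.1 to 39.4% of all listed transcripts, those at 0 included, had an estimated count that was not whole. The authors deposited these estimated counts without further normalization, and the deposited TPM values are scaled for effective length and library total. Transcripts were joined to genes by their identifiers with the GENCODE M21 annotation of the same build. A total of 569 transcripts had no gene there, and they held at most 0.0662% of the reads of any library. They were left out. The remainder gave 35498 genes, and coordinates are those of GENCODE M21 on GRCm38, counted from 1.

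Estimated counts were summed per gene and rounded to whole numbers. Genes with too few reads were removed with edgeR's filterByExpr, which left 14238 genes. Libraries were scaled with TMM factors, which lay between 0.918 and 1.06. Genotype was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) without further covariates, and p-values were adjusted with the Benjamini-Hochberg method. An adjusted p under 0.05 was taken as changed. Fold changes are KO over WT, standard errors (SE) are the absolute log2 fold change divided by the square root of the test's F value, and levels are CPM, reads scaled by the TMM-adjusted library size, as mean ± SD over 3 KO and 4 WT libraries.

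Before the data were examined, 32 gene lists were fixed, and 31 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 31 lists. The same test with an estimated correlation, and the rotation test fry, were computed beside it. Results of fry are for a shift in 1 direction, unless its form that ignores direction is named. Counts of changed members were also made with p-values adjusted over the list alone. Values of a list per library are medians over its members of log2(CPM + 0.5) minus the WT mean. The share of changed genes among those starting within 10 Mb of Aim2 was compared with the share among other genes by a two-sided Fisher's exact test, with Aim2 left out. Reads shared between similar genes are split by Salmon's model, so values of gene families such as the IFI200 and immunoglobulin genes are uncertain between members.

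The genes to be named were fixed by a rule before the data were examined. They were Aim2 and each tested IFI200 family member, the 10 largest increases and 10 largest decreases among changed genes with a mean of at least 1 CPM and no overlap between the groups, and the 2 to 4 members of each list with the smallest p. The number per list was set after the gene-level results were known, at 4 for lists past the camera threshold and 2 for the others. Other genes were named after their values were seen, which is said where it applies. The values of some genes that the rule names are not reported here.

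On simulated counts for the 14238 genes, the same steps called 64.6% of 99 tested genes changed 2-fold and 95% of 100 tested genes changed 4-fold. Of 174 calls, 5.17% were unchanged genes. A list of 30 genes raised 1.5-fold gave a camera p of 4.39e-31 and a list of 30 unchanged genes gave 0.609. The simulated genes were drawn independently of each other. In the data the estimated correlation within a list reached 0.973 (skeletal muscle), so the simulation does not show how often camera calls correlated lists falsely.

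Alternatives were RLE scaling, scaling without haemoglobin, immunoglobulin and mitochondrially encoded genes, the Wald test of DESeq2 1.42.0, limma voom with sample weights, other filters, an offset for effective transcript length, limma on log2(TPM + 0.1) and log2(TPM + 1), other thresholds and windows, the sample number as a block, and leaving out each library in turn. A fit without immunoglobulin genes and a Fisher's exact test without the IFI200 family, also with each library left out, were added after the results were seen. Depth was 20300468 to 21099972 estimated reads per library, and genes with few reads, such as several adipocyte markers, were left untested by the filter. Counting intervals are exact at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.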

Results

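Gene expression was measured in bone marrow of female mice aged 5 to 6 months, in 3 libraries labelled Aim2 KO and 4 labelled WT. Aim2 encodes a sensor of cytosolic DNA that starts assembly of an inflammasome. By its title, the study was concerned with the formation of adipocytes in marrow after loss of Aim2. The KO libraries held 20777315, 21027429 and 20948822 estimated reads and the WT libraries 20342443, 20558800, 20300468 and 21099972. Haemoglobin genes took 11.3 to 13.7% of the reads in KO and 13.8 to 19.9% in WT, with the highest share in WT library 1. No pair of libraries of 1 group agreed within sampling noise, with a chi-square per degree of freedom of 9.52 to 58.8. The labels do not say that each library came from its own mouse, so p-values measure the spread between these libraries.

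Aim2 itself was lower in each library labelled KO than in each WT library. The gene (ENSMUSG00000037860.15) lies on the plus strand of chromosome 1 (173350879 to 173466040). It had 157, 47 and 59 reads in KO libraries 1 to 3 against 601, 573, 535 and 533 reads in the WT libraries. The level was 4.10 ± 2.84 CPM (SD, n = 3) in KO and 27.9 ± 3.07 CPM (SD, n = 4) in WT, a log2 fold change of -2.76 ± 0.38 (SE; adjusted p = 0.028, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). KO library 1 kept 26.5% of the WT mean, against 8.11% and 9.58% in KO libraries 2 and 3. Most WT reads went to the protein-coding transcript Aim2-204 (173455354 to 173466032), with 404 to 524 estimated reads in each WT library. That transcript had 95.3 reads in KO library 1 and 0 in KO libraries 2 and 3, which allows up to 3 reads in each. The transcript Aim2-205, which ends within the gene (173420598 to 173459719), had 22.99 to 44.0 reads in KO and 34.0 to 46.2 in WT. Which part of the gene was deleted is not given in the labels, so reads outside that part say nothing about the genotype. The call for Aim2 was lost when any library other than KO library 1 was left out (adjusted p = 0.0538 to 0.097), while the Aim2 log2 fold change stayed between -3.49 and -2.47. An offset for transcript length moved it to -1.28 and TPM values to -1.17 or -1.08, depending on the pseudocount (adjusted p = 0.054 to 0.109 with and without a filter).

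In the comparison of KO with WT marrow, 92 of 14238 tested genes changed, 68 higher and 24 lower in KO. Of these, 36 rose and 16 fell by at least 2-fold. All 92 had no overlap between the KO and WT libraries, against 12.9% of all tested genes and 5.71% by chance. The 92 were called from the same values, so their separation largely follows from the call and is no independent support. Without adjustment, p was under 0.05 for 1631 genes. With 1 library left out the count was 42 (33 higher, 9 lower) without KO library 1, 22 (21 and 1) without KO library 2, 65 (45 and 20) without WT library 1, 17 (16 and 1) without WT library 2, 24 (22 and 2) without WT library 3 and 51 (44 and 7) without WT library 4. With limma on TPM values, which shifted the median log2 fold change of all genes by 0.131 to 0.143, the share of higher genes among the changed ones was 87.8 to 90% rather than 73.9%, and without a filter on low values 71.4%. DESeq2 called 398 genes and voom with sample weights 305, of which 63.1% and 60% were higher.

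Among changed genes with a mean of at least 1 CPM, the largest increases were in Ifi202b, in immunoglobulin genes, in Oas1g and in Cd300e. Ighg2c, the constant region of the IgG2c antibody heavy chain (chromosome 12, 113285325 to 113288932), was at 708 ± 349 CPM (SD, n = 3) in KO and 90.0 ± 37.4 CPM (SD, n = 4) in WT. Its log2 fold change was 2.98 ± 0.44 (SE; adjusted p = 0.035). The variable segments Igkv8-16, Ighv1-11, Igkv6-23, Ighv1-15, Igkv3-2 and Ighv10-1 rose by 2.17 to 4.98 on the log2 scale, with adjusted p from 0.029 to 0.049. Oas1g, a member of the oligoadenylate synthetase family induced by interferon (chromosome 5, 120876142 to 120887613), was at 17.6 ± 5.12 CPM in KO and 2.34 ± 0.47 CPM in WT (log2 fold change 2.91 ± 0.22, SE; adjusted p = 0.00422). Cd300e, a receptor of monocytes, rose with a log2 fold change of 2.41 ± 0.26 (SE; adjusted p = 0.011). When each library was left out in turn, Ifi202b and Oas1g passed in all 7 fits and Cd300e in 6, without WT library 2 being the exception at an adjusted p of 0.0515. The 7 immunoglobulin genes passed in 1 to 3 of the 7 fits, with adjusted p up to 0.176.

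Among changed genes with a mean of at least 1 CPM, the largest decreases after those of Ifi213 and Aim2 were in Mid1, an X-linked ubiquitin ligase of microtubules, and Cdkn1c, an inhibitor of cyclin-dependent kinases. Mid1 (chromosome X, 169685199 to 170005736) was at 5.42 ± 0.51 CPM in KO and 30.4 ± 15.3 CPM in WT (log2 fold change -2.49 ± 0.36, SE; adjusted p = 0.032). WT library 1 held 52.6 CPM of Mid1 and the other WT libraries 19.2 to 28.3 CPM. Cdkn1c was at 4.05 ± 0.22 CPM in KO and 12.4 ± 3.66 CPM in WT (-1.61 ± 0.25, SE; adjusted p = 0.037). Nsg2, Dock3, the lymph node homing receptor Ccr7, the aminopeptidase Anpep, the dendritic cell lectin Cd209a and Ifi209 fell with log2 fold changes between -1.52 and -1.28. Ifi213 passed in all 7 fits with a library left out, and the others of this group passed in 0 to 3 of them. For Mid1 the call was lost without KO library 1 (adjusted p = 0.0979), KO library 2 (0.142), KO library 3 (0.0692), WT library 2 (0.0565) or WT library 3 (0.0966).

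The IFI200 family, to which Aim2 belongs, is a cluster of interferon-inducible genes on chromosome 1, and its members moved in both directions. Of 13 tested members 2 were higher, 4 were lower and 7 did not pass. Adjusted over the list alone, 5 were higher and 6 lower. Ifi202b (173962568 to 173982744) had 505, 443 and 662 reads in the KO libraries and 2, 0, 0 and 0 in the WT libraries, a ratio of 1013 with a counting interval of 280 to 8370 (adjusted p = 1.44e-04). Ifi205 rose from 1.89 ± 0.41 CPM in WT to 6.31 ± 1.53 CPM in KO (log2 fold change 1.73 ± 0.23, SE; adjusted p = 0.027). Ifi213 (173566283 to 173599274) had 9, 5 and 4 reads in KO against 103 to 160 in WT, a log2 fold change of -4.48 ± 0.31 (SE; adjusted p = 0.00264). Ifi209 and Ifi211 fell with log2 fold changes of -1.28 and -1.01. Ifi206, Ifi208, Ifi214, Ifi204, Ifi203, Ifi207 and Mndal had log2 fold changes of -1.50, -1.27, 1.30, 0.62, 0.40, -0.10 and 0.17 and did not pass, and Ifi207 changed sign under some alternatives. When libraries were left out, Ifi202b and Ifi213 passed in all 7 fits, Ifi205 in 2, Ifi209 in 1 and Ifi211 in 0. The family as a whole did not pass camera (adjusted p = 0.545). Camera looks for a shift in 1 direction, so it does not show whether a family that moved both ways changed. The form of fry that ignores direction gave an adjusted p of 4.56e-05 for the family, Aim2 included. The median log2 fold change of the family (-0.10) and its mean (0.11) differed in sign, where the mean rests on the fitted value of Ifi202b. Reads shared between members leave the split among them uncertain.

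**Figure D1:**
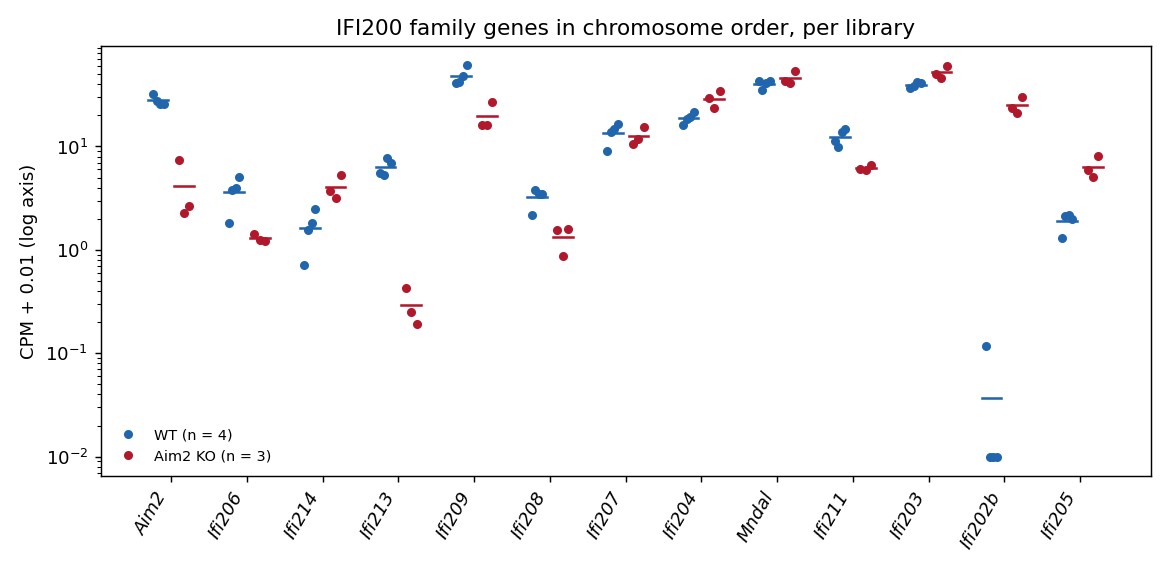
Expression of the IFI200 family genes in chromosome order, as CPM + 0.01 on a log axis, with 1 point per library and a bar at the mean of the 4 WT (blue) or 3 Aim2 KO (red) libraries. Ifi202b lies near the floor in WT, where 3 of the 4 libraries had 0 reads, and at 21.3 to 29.9 CPM in KO, while Ifi213 is at 5.23 to 7.75 CPM in WT and at most 0.422 CPM in KO.

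Interferon-stimulated genes were higher in KO marrow as a group by camera with the preset correlation, while the adjusted p was 0.132 with an estimated correlation. Of the 31 tested list members, 20 rose and 0 fell, with 11 not passing, and 30 were higher when adjusted over the list alone. Each of the 31 had a log2 fold change above 0, with a median of 0.98. Oas2, an oligoadenylate synthetase that senses double-stranded RNA, was at 36.7 ± 6.03 CPM (SD, n = 3) in KO and 8.65 ± 2.29 CPM (SD, n = 4) in WT (log2 fold change 2.09 ± 0.21, SE; adjusted p = 0.00877). Oas1a rose 3.48-fold (adjusted p = 0.00665), Usp18, which removes the ubiquitin-like modifier Isg15 from proteins, rose 2.46-fold (adjusted p = 0.00561), and the RNA helicase Dhx58 rose 1.97-fold (adjusted p = 0.00778). Irf7 and Stat2, which carry interferon signalling to transcription, rose 2.32-fold and 1.37-fold, and each passed in 2 of the 7 fits with a library left out (adjusted p up to 0.104). Isg15 and Mx1 were at 1.98-fold and 1.78-fold and did not pass (adjusted p = 0.0984 and 0.0546). Irf7, Stat2, Isg15, Mx1 and Bst2 were chosen after their values were seen. The list median lay 0.91 to 1.09 above the WT mean in the KO libraries and between -0.12 and 0.23 in the WT libraries.

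The interferon-stimulated list passed camera with an adjusted p of 1.26e-47 and fry with an adjusted p of 0.00403. With an estimated correlation the unadjusted p was 0.00427. With 1 library left out the list median stayed between 0.86 and 1.04, and 8 to 18 members passed. The count moved by over 1.5 times without KO library 1 (13), KO library 2 (8), WT library 2 (8) and WT library 3 (12). Oas1a, Oas2, Usp18 and Dhx58 passed in all 7 of these fits.

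**Figure D2:**
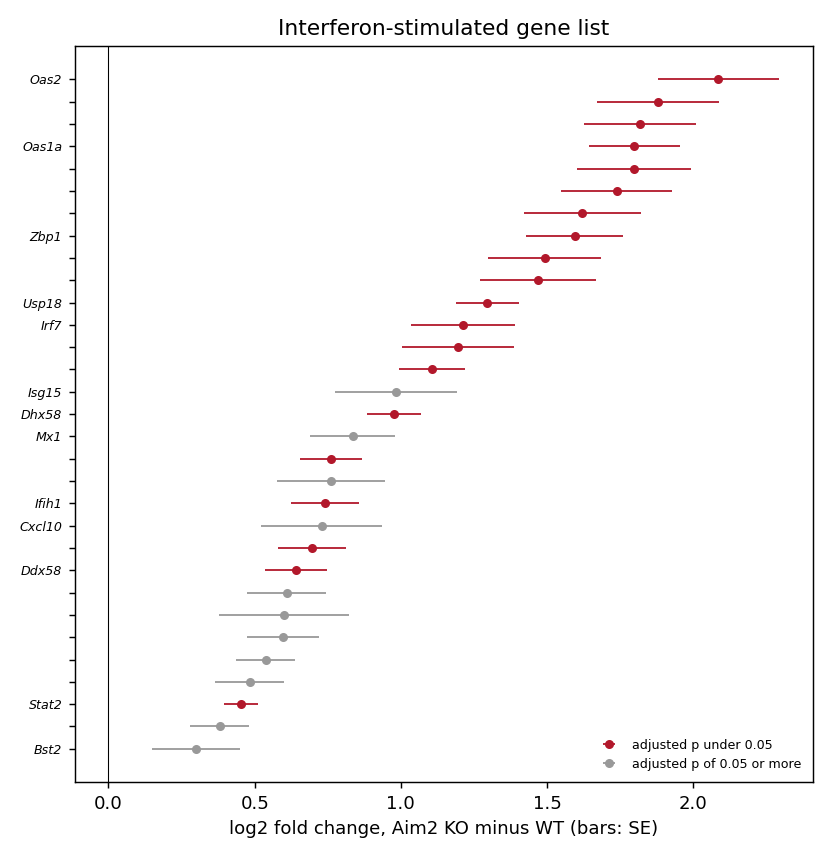
Log2 fold change (Aim2 KO minus WT) of the 31 interferon-stimulated list members, with bars for the SE of the edgeR fit on 3 KO and 4 WT libraries, members past an adjusted p of 0.05 in red, and names for the members the text describes. The values run from 0.30 for Bst2 to 2.09 for Oas2, and each lies above 0.

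Among sensors of nucleic acid in the cytosol some were higher in KO. Of 12 tested members of this list 4 were higher, 0 were lower and 8 did not pass, and 6 were higher and 1 lower when adjusted over the list alone. The 4 were Zbp1 (3.02-fold, adjusted p = 0.010), Dhx58, Ifih1 (1.67-fold, adjusted p = 0.039) and Ddx58 (1.56-fold, adjusted p = 0.048), which all stand on the interferon-stimulated list too. The list had a camera adjusted p of 3.21e-05, and an adjusted p of 0.322 with an estimated correlation. The count was 2 without KO library 1, KO library 2, WT library 1, WT library 2 or WT library 3, since Ifih1 and Ddx58 each passed in 1 of the 7 fits (adjusted p up to 0.172), while Zbp1 and Dhx58 passed in all 7.

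For inflammasome and pyroptosis genes 0 of 18 passed, with 2 higher when adjusted over the list alone. Before any adjustment, p was under 0.05 for 5 (4 higher, 1 lower), with DESeq2 2 and with voom weights 1. Casp4, the caspase that responds to lipopolysaccharide inside cells, was at 13.96 ± 1.82 CPM in KO and 8.98 ± 0.90 CPM in WT (adjusted p = 0.081), and Il1b had a log2 fold change of 0.77 (adjusted p = 0.107). Ninj1 and Gsdmd had log2 fold changes of -0.34 and 0.15. The list had a camera adjusted p of 0.00349, and an adjusted p of 0.516 with an estimated correlation. NF-kB target genes had 0 of 14 members past the test, 1 higher over the list alone, a camera adjusted p of 0.029 and an adjusted p of 0.564 with an estimated correlation, with log2 fold changes of 0.73 for Cxcl10, 0.34 for Tnf and 0.61 for Ccl2. At an unadjusted p under 0.05 there were 2 NF-kB targets, with DESeq2 1 and with voom weights 1. The list call was lost without KO library 1 (adjusted p = 0.0971), KO library 3 (0.252), WT library 1 (0.189) or WT library 2 (0.0738).

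Of 16 listed markers of mature adipocytes only 9 had enough reads to be tested, and these did not differ past the threshold. Of 9 tested members 0 passed, also when adjusted over the list alone, and the median log2 fold change was -0.03. Adipoq, the adipokine adiponectin, was at 47.8 ± 5.58 CPM (SD, n = 3) in KO and 53.6 ± 2.36 CPM (SD, n = 4) in WT (log2 fold change -0.16 ± 0.09, SE; adjusted p = 0.524). Cidec, a lipid droplet protein, was at 0.71 ± 0.86 CPM in KO and 0.35 ± 0.34 CPM in WT (adjusted p = 0.765). The list did not pass camera (adjusted p = 0.48), and 0 members had an unadjusted p under 0.05 or passed with DESeq2 or voom weights. The list median lay between -0.23 and 0.22 over the fits, highest without KO library 1, where 11 members were tested, and it differed in sign from the mean of 0.06. The list medians of the KO libraries were -0.07, -0.31 and 0.44, a wider range than the -0.12 to 0.14 of the WT libraries. KO library 3, the highest, was also highest on the skeletal muscle list (1.96). KO libraries 1 and 2 stood in the opposite order on that list (-4.66 and -0.92). A total of 7 members had too few reads to be tested, and all 36 reads of Plin4 were in WT library 3 (1.74 CPM). Among the others were Plin1, with 29 reads over the KO libraries and 26 over the WT libraries, and Lep, with 6 and 0, of which KO library 3 held 23 and 6. Plin4, Plin1 and Lep were named after their values were seen, and differences in them were not tested.

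Regulators of adipogenesis and lipid genes did not differ past the threshold either. Of 18 adipogenic regulators 0 passed (camera adjusted p = 0.453), with log2 fold changes of 0.30 ± 0.12 (SE) for Klf4 and 0.26 for Zfp423, and their median (0.08) and mean (-0.01) differed in sign. None of 5 tested brown adipocyte genes passed (camera adjusted p = 0.137), with -0.61 ± 0.79 (SE) for Ppargc1a and -0.08 for Dio2. Ucp1, Cidea and Elovl3 of that list had too few reads to be tested. They had 4, 4 and 3 reads over the KO libraries and 3, 19 and 7 over the WT libraries. These 3 were named after their values were seen, and the list results do not cover them. Ppargc1a had 19 reads in KO library 3 against 1 and 3 in the other KO libraries. Its log2 fold change was -2.45 without KO library 3 and -0.10 without KO library 1. The brown adipocyte list passed camera without KO library 3 (adjusted p = 0.0347). Its list median was -0.90, -0.66 and 0.42 in KO libraries 1 to 3. The skeletal muscle list ran in the same order, at -4.66, -0.92 and 1.96, and a common cause was not tested. Of 21 genes of fatty acid and triglyceride handling 0 passed (camera adjusted p = 0.461), and Scd1, which makes monounsaturated fatty acids, was at 31.9 ± 6.47 CPM in KO and 52.6 ± 11.8 CPM in WT (adjusted p = 0.201), while Mgll had a log2 fold change of -0.28. Fatty acid oxidation genes gave 0 of 18 (camera adjusted p = 0.453), with 0.21 for Slc25a20, and the list median lay slightly under 0 while camera put the list up. Cholesterol synthesis genes gave 0 of 19, with 1 higher when adjusted over the list alone (camera adjusted p = 0.261), and Hsd17b7 was at 0.76 ± 0.15 (SE; adjusted p = 0.090). The cholesterol list passed without KO library 1 (adjusted p = 0.0039). The counts of 0 in these 5 lists are from edgeR's quasi-likelihood test over all genes. Without adjustment, p was under 0.05 for 1 adipogenic regulator, 0 brown adipocyte genes, 1 gene of fatty acid and triglyceride handling, 1 of fatty acid oxidation and 2 of cholesterol synthesis. DESeq2 called 1 in the handling list and 1 in the cholesterol list, and voom weights 1 in the cholesterol list.

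Genes of the B lineage were lower in KO as a group by camera with the preset correlation (adjusted p = 1.36e-10), while the adjusted p was 0.37 with an estimated correlation and single members did not pass over all genes. Each of the 15 tested members had a log2 fold change under 0, with a median of -0.95, and 0 of 15 passed. Adjusted over the list alone 12 were lower, as at an unadjusted p under 0.05, and with DESeq2 8 and with voom weights 6 were lower. Pax5, the transcription factor that fixes B cell identity, was at 18.7 ± 5.40 CPM (SD, n = 3) in KO and 43.2 ± 7.90 CPM (SD, n = 4) in WT (log2 fold change -1.21 ± 0.22, SE; adjusted p = 0.068). Il7r, Cd79a and Cd79b were at -1.16, -0.98 and -0.95 with adjusted p from 0.083 to 0.087. The list median was -0.82, -1.32 and -0.62 in the KO libraries and between -0.32 and 0.44 in the WT libraries.

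Plasma cell genes were higher in KO as a list by camera with the preset correlation (adjusted p = 1.84e-04), while the adjusted p was 0.516 with an estimated correlation and single members did not pass over all genes. Of 10 tested members 0 passed, 5 were higher when adjusted over the list alone, and the median was 0.37. Before any adjustment, p was under 0.05 for 6, with DESeq2 2 and with voom weights 0. Xbp1, a transcription factor of antibody-secreting cells, was at 169 ± 22.7 CPM in KO and 121 ± 15.9 CPM in WT (adjusted p = 0.181), and Prdm1, Jchain and Tnfrsf17 were at 0.59, 0.57 and 1.19.

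T and NK cell genes had a median of -0.33, with 0 of 16 past the test and 4 lower over the list alone (camera adjusted p = 0.00381, adjusted p = 0.543 with an estimated correlation). Cd8a, Cd8b1, Cd4 and Lck were at -0.92, -1.08, -0.70 and -0.36, and the list call was lost without KO library 3 (adjusted p = 0.0931). At an unadjusted p under 0.05 there were 8 T and NK cell genes (7 lower, 1 higher), with DESeq2 3 and with voom weights 2. In the list of dendritic cell and MHC class II genes 1 of 15 fell, also over the list alone, and 14 did not pass. It was Cd209a, at 2.33 ± 0.28 CPM in KO and 5.96 ± 0.81 CPM in WT (adjusted p = 0.021), which passed in 2 of the 7 fits with a library left out. The call was lost without KO library 1 (adjusted p = 0.0554), KO library 2 (0.0913), WT library 2 (0.0515), WT library 3 (0.068) or WT library 4 (0.051). The class II genes H2-Eb1, H2-Ab1 and H2-Aa were at -0.74, -0.67 and -0.67 and did not pass. The list had a camera adjusted p of 0.00349, and an adjusted p of 0.543 with an estimated correlation.

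**Figure D3:**
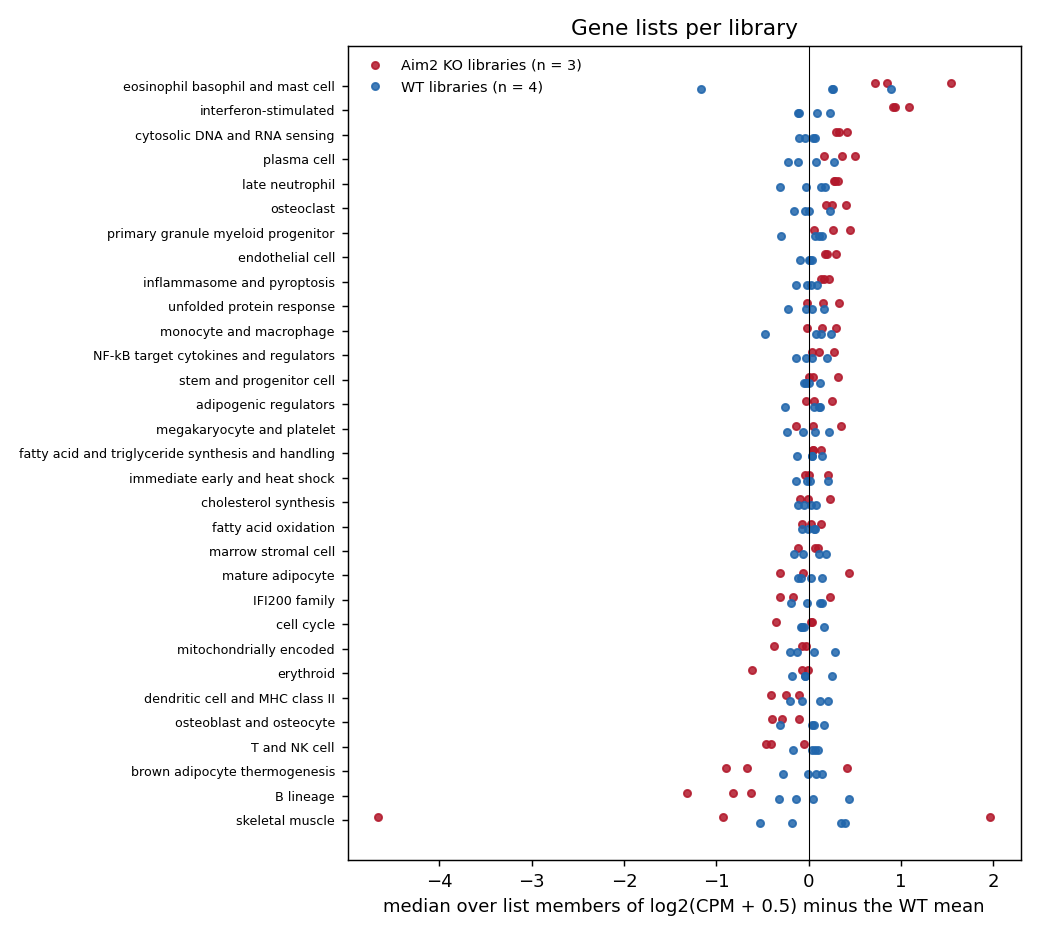
Median over the tested members of each gene list of log2(CPM + 0.5) minus the WT mean, with 1 point per library for 3 Aim2 KO (red) and 4 WT (blue) libraries. The interferon-stimulated list stands apart between the groups by 0.681, and the skeletal muscle list spreads from -4.66 to 1.96 among the KO libraries.

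Osteoblast and osteocyte genes had a median of -0.29, with 0 of 18 past the test and 6 lower when adjusted over the list alone. Bglap, which encodes osteocalcin, was at 56.6 CPM in KO and 145 CPM in WT (log2 fold change -1.36 ± 0.34, SE; adjusted p = 0.16), and Col1a1, Bglap2 and Phex were at -0.76, -1.15 and -0.59. The camera adjusted p was 0.024, and the adjusted p was 0.564 with an estimated correlation. The list call was lost without KO library 1 (adjusted p = 0.137), WT library 1 (0.235) or WT library 2 (0.0728), and WT library 4 had a list median of -0.31, within the -0.39 to -0.10 of the KO libraries. Without adjustment, p was under 0.05 for 8 (6 lower, 2 higher), with DESeq2 3 and with voom weights 0.

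Osteoclast genes had a median of 0.31, with 0 of 12 past the test and 1 higher over the list alone (camera adjusted p = 0.00381, adjusted p = 0.368 with an estimated correlation), and Mmp9, Oscar, Ocstamp and Acp5 were at 0.51, 0.51, 0.81 and 0.35. Before any adjustment, p was under 0.05 for 5 osteoclast genes, with DESeq2 1 and with voom weights 1. Endothelial genes had a median of 0.22, with 0 of 12 past the test and 5 higher over the list alone (camera adjusted p = 7.82e-06, adjusted p = 0.159 with an estimated correlation). Stab2, a scavenger receptor of sinusoidal endothelium, was at 62.9 ± 4.54 CPM in KO and 48.2 ± 2.92 CPM in WT (adjusted p = 0.084), and Kdr, Flt4 and Cdh5 were at 0.25, 0.57 and 0.40. At an unadjusted p under 0.05 there were 7 endothelial genes, with DESeq2 2 and with voom weights 2. Marrow stromal genes gave 0 of 14 (camera adjusted p = 0.222), with -0.51 for Grem1 and 0.26 for Pdgfrb, with 1 at an unadjusted p under 0.05 and 0 with DESeq2 or voom weights. Of the chondrocyte list only 3 members were tested, too few for a list test, and Col11a1 and Col2a1 were at -1.10 and -0.79 without passing.

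Muscle genes varied between the KO libraries. The skeletal muscle list had a median of -4.66, -0.92 and 1.96 in KO libraries 1 to 3, against -0.53 to 0.39 in the WT libraries. Its median log2 fold change was 0.50 while camera put the list down (adjusted p = 0.032), so the signs differed. The adjusted p was 0.711 with an estimated correlation, and 0 of 14 members passed, also over the list alone, at an unadjusted p under 0.05, with DESeq2 and with voom weights. Myh4, Pvalb, Eno3 and Mylpf were at 1.06, 0.96, 0.44 and 0.49 with SE from 0.71 to 1.07. Without KO library 1 the list median was 1.05 and camera put the list up (adjusted p = 0.128), and the median was -1.91 without KO library 3. The call was also lost without WT library 2 (adjusted p = 0.0728) or WT library 4 (0.0954).

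Granulocyte and monocyte genes were slightly higher as lists by camera with the preset correlation, with 0 members past the test over all genes. Late neutrophil genes had a median of 0.27, 0 of 16 past the test and 1 higher over the list alone (camera adjusted p = 2.31e-06, adjusted p = 0.516 with an estimated correlation), and Mmp9, Retnlg, Cxcr2 and Cd177 were at 0.51, 0.26, 0.44 and 0.40. Without adjustment, p was under 0.05 for 5 late neutrophil genes, with DESeq2 1 and with voom weights 1. Genes of primary granule progenitors had a median of 0.27 and 0 of 10 past the test (camera adjusted p = 0.00253, adjusted p = 0.543 with an estimated correlation), with Nkg7, Hdc, Cst7 and Ms4a3 at 0.28, 0.42, 0.32 and 0.26. Before any adjustment, p was under 0.05 for 3 of these, with DESeq2 and voom weights 0. WT library 1 stood below the other WT libraries on both lists, with a median of -0.31 against -0.03 to 0.18 for late neutrophil genes and -0.30 against 0.07 to 0.15 for primary granule genes, and KO library 1 (0.06) lay below these 3 WT libraries on the primary granule list. Both lists passed without WT library 1, with medians of 0.20 and 0.22, and the primary granule median was 0.16 without KO library 3.

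Monocyte and macrophage genes had a median of 0.12, 0 of 18 past the test and 1 higher over the list alone (camera adjusted p = 0.0155, adjusted p = 0.645 with an estimated correlation). Fcgr1, an IgG receptor, was at 22.5 ± 4.45 CPM in KO and 10.98 ± 2.23 CPM in WT (adjusted p = 0.066), and Ly6c2, Ccr2 and Csf1r were at 0.60, 0.31 and 0.35. At an unadjusted p under 0.05 there were 3 monocyte genes, with DESeq2 1 and with voom weights 1. WT library 1 had a list median of -0.48 against 0.08 to 0.24 in the other WT libraries, and the list call was lost without it (adjusted p = 0.671) or without KO library 1 (0.321). Genes of eosinophils, basophils and mast cells had a median of 0.72 and 0 of 12 past the test (camera adjusted p = 0.00938, adjusted p = 0.564 with an estimated correlation), and WT library 1 had a list median of -1.16 against 0.25 to 0.89 in the other WT libraries. Ear2, Fcer1a, Cpa3 and Prss34 were at 1.33, -0.52, 0.40 and 0.32. Without adjustment, p was under 0.05 for 1, with DESeq2 and voom weights 0, and the list call was lost without KO library 2 (adjusted p = 0.0553) or KO library 3 (0.0722).

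In the erythroid list 0 of 16 members passed, and the median was -0.22 (camera adjusted p = 0.00349, adjusted p = 0.618 with an estimated correlation), with Klf1, Hba-a2 and Hbb-bt at -0.33, -0.45 and -0.39. Before any adjustment, p was under 0.05 for 2 erythroid genes (1 higher, 1 lower), while DESeq2 called 1 lower and voom weights 1 higher. The list median was -0.61 in KO library 3 and -0.07 and -0.00412 in the other KO libraries, and the list call was lost without KO library 3 (adjusted p = 0.867). Megakaryocyte and platelet genes gave 0 of 11 (camera adjusted p = 0.057), with 0.32 for Gp1ba and 0.33 for Tubb1, 2 at an unadjusted p under 0.05 and 0 with DESeq2 or voom weights. That list passed without KO library 1 (adjusted p = 0.00119) or WT library 2 (0.00233).

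In the list of stem and progenitor cells 1 of 11 rose, also over the list alone, and 10 did not pass. It was Slamf1, a surface receptor of stem cells and lymphocytes (chromosome 1, 171767127), at 45.0 ± 6.92 CPM in KO and 22.2 ± 1.46 CPM in WT (adjusted p = 0.011), and it passed in 6 of the 7 fits with a library left out, but not without KO library 2 (adjusted p = 0.0558). Cd34 and Myct1 were both at 0.19. The list had a camera adjusted p of 0.039, and an adjusted p of 0.564 with an estimated correlation. The list call was lost without KO library 3 (adjusted p = 0.652), WT library 1 (0.147), WT library 3 (0.074) or WT library 4 (0.0596).

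Lists for proliferation, stress and handling had 0 members past the test over all genes. Cell cycle genes had a median of -0.10 (0 of 24, camera adjusted p = 0.039, adjusted p = 0.739 with an estimated correlation), with E2f1, Pcna, Birc5 and Aurka at -0.16, -0.16, -0.23 and -0.15. The list call was lost without KO library 3 (adjusted p = 0.288, list up) or WT library 1 (0.576). Genes of the unfolded protein response had a median of 0.16 (0 of 12, camera adjusted p = 0.015, adjusted p = 0.564 with an estimated correlation), with Creld2, Hsp90b1 and Calr at 0.35, 0.17 and 0.16. That call was lost without KO library 3 (adjusted p = 0.146) or WT library 1 (0.054). Immediate early and heat shock genes gave 0 of 14, with 1 higher over the list alone (camera adjusted p = 0.48), and Nr4a1 and Fos were at 0.79 and 0.66. Mitochondrially encoded genes had a median of -0.11 (0 of 13, camera adjusted p = 0.039, adjusted p = 0.592 with an estimated correlation), with mt-Co3, mt-Nd3, mt-Nd6 and mt-Nd4l at -0.75, -0.44, -1.28 and 0.42. The mitochondrial list call was lost without KO library 1 (adjusted p = 0.399), WT library 1 (0.2) or WT library 2 (0.0728). At an unadjusted p under 0.05 there were 0 cell cycle genes, 1 gene of the unfolded protein response, 3 immediate early and heat shock genes and 3 mitochondrial genes, and DESeq2 called 0, 1, 1 and 1 and voom weights 0, 0, 0 and 1.

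In all, 21 of 31 lists passed camera with the preset correlation and 0 passed with an estimated correlation. For a shift in 1 direction, 3 passed fry (interferon-stimulated, endothelial, and cytosolic DNA and RNA sensing). The form of fry that ignores direction put further lists past the threshold. Among them were the IFI200 family (adjusted p = 4.56e-05), inflammasome and pyroptosis (0.00151) and B lineage (0.0281). Other divisions of the 7 libraries into 3 and 4 gave up to 23 lists past camera with the preset correlation.

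Changed genes were concentrated on chromosome 1 around Aim2. Among 168 tested genes starting within 10 Mb of Aim2, 11 changed (6.55%), against 80 of 14069 other genes (0.569%). The 11 were Uap1, Cfap126, Pcp4l1, Itln1, Slamf1, Ifi213, Ifi209, Ifi211, Ifi202b, Ifi205 and Psen2, of which 6 were higher and 5 lower. The odds ratio was 12.2 (95% interval 5.76 to 23.7, p = 9.31e-09, Fisher's exact test). Itln1, which encodes intelectin-1 (171518122 to 171535294), had 104 reads over the KO libraries and 1 over the WT libraries, a ratio of 131 with a counting interval of 23 to 5220. Uap1 and Psen2 fell by less, with log2 fold changes of -0.39 and -0.47, and Cfap126 and Pcp4l1 rose with 1.30 and 0.98. When libraries were left out, Uap1 and Pcp4l1 passed in 0 of the 7 fits, Cfap126 in 1, Psen2 in 2 and Itln1 in 6. Of the non-family genes, all but Slamf1 were named after their values were seen. With 1 library left out the count near Aim2 was 5 without KO library 1, 3 without KO library 2, 3 without WT library 2, 4 without WT library 3 and 4 without WT library 4, where the odds ratio was 7.23. Without the other IFI200 family members 6 of 156 genes changed and the odds ratio was 6.99 (95% interval 2.45 to 16.3, p = 3.61e-04, Fisher's exact test). With a library left out as well, that count of 6 was 3 without KO library 1, 1 without KO library 2 (odds ratio 4.77, p = 0.198), 4 without KO library 3, 6 without WT library 1, 1 without WT library 2 (6.51, p = 0.152), 2 without WT library 3 and 2 without WT library 4 (3.85, p = 0.102; Fisher's exact test).

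**Figure D4:**
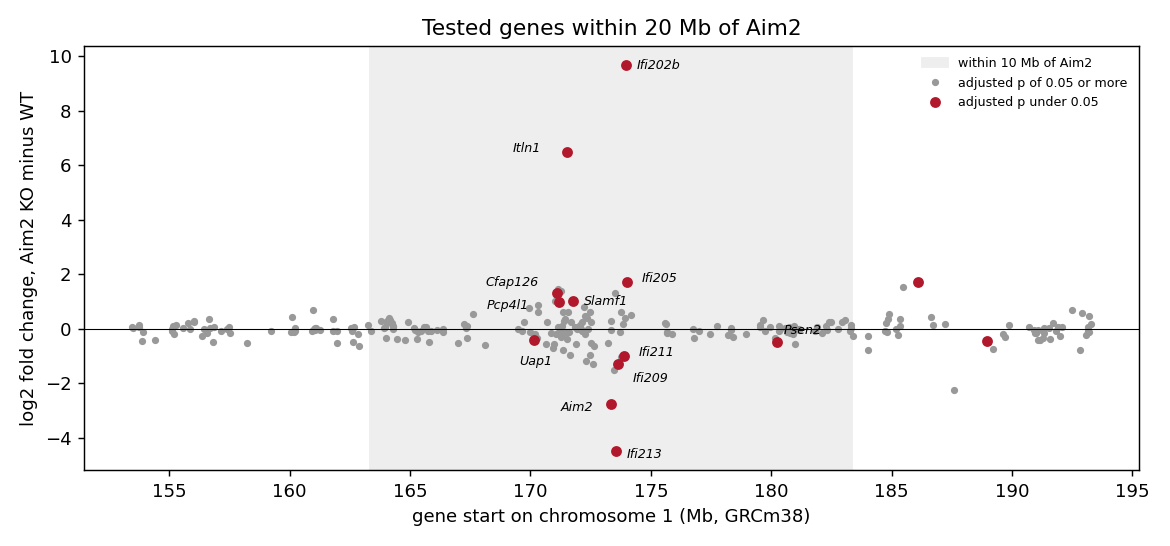
Log2 fold change (Aim2 KO minus WT) of the tested genes within 20 Mb of Aim2 against the gene start on chromosome 1 in Mb (GRCm38), with genes past an adjusted p of 0.05 in red and the 10 Mb on either side of Aim2 shaded. The 11 changed neighbours lie on both sides of 0, and the fitted values of Ifi202b and Itln1 rest on 2 and 1 reads over the WT libraries.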

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

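In the 4 WT libraries, 163 values were checked for 1 library far from the other 3, by the gap to the nearest library over the whole range, and 8 lay above the 95% critical value of Dixon's test. Chance gives about 1 in 20, and this number is close to that. The values come from the same 4 libraries and are not independent, so the number does not show that the flags are chance. Of the 8, 7 were in WT library 1, which also had the highest haemoglobin share (19.9%). The KO libraries, a group of 3, were not checked in this way.

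In WT library 1, Ifi202b had 2 reads and the other WT libraries 0, a gap ratio of 1 that rests on those 2 reads. Ighg2c was lowest there, at 34.3 CPM against 105 to 115 CPM (gap ratio 0.875). The monocyte genes Ly6c2 and Csf1r were lowest there too, at 211 CPM against 349 to 360 CPM (0.93) and at 92.0 CPM against 137 to 143 CPM (0.872). Fos was at 4.24 CPM against 8.14 to 8.63 CPM (0.888). The mitochondrial gene mt-Co3 was highest there, at 1195 CPM against 756 to 814 CPM (0.869), and so was the cell cycle list median, at 0.16 against -0.08 to -0.05 (0.851). In WT library 3, the plasma cell gene Tnfrsf17 was highest, at 1.31 CPM against 0.643 to 0.679 CPM (0.947).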

How the results depend on the processing

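The fit without immunoglobulin genes and the neighbourhood tests without the IFI200 family were chosen after the results were seen, and the others before the data were examined. Against 92 changed genes (68 higher, 24 lower), DESeq2 gave 398 (251 and 147), voom with sample weights 305 (183 and 122), the length offset 55 (44 and 11), log2(TPM + 0.1) 49 (43 and 6), log2(TPM + 1) 50 (45 and 5), and TPM without a filter 28 (20 and 8). A 2-fold minimum gave 52 and an adjusted p under 0.1 gave 198. RLE scaling, scaling without abundant genes, the other filters and the fit without immunoglobulin genes gave 77 to 121. With 1 library left out the counts were 17 to 65 changed, 16 to 47 higher and 1 to 20 lower, where fewer samples enter each fit. The log2 fold change of Aim2 was -1.17 with log2(TPM + 0.1), with and without a filter, and -1.08 with log2(TPM + 1), no longer past the threshold (adjusted p = 0.054 to 0.109), and the Aim2 log2 fold change was -3.49 to -2.47 with 1 library left out. Lists past the threshold numbered 0 with an estimated correlation, 3 with fry, and 14 to 20 with 1 library left out. With the family kept, and without it in all 7 libraries, the odds ratio near Aim2 kept its side of the threshold in each alternative run, at 20.2 within 5 Mb, 8.93 within 20 Mb, 7.60 with DESeq2, 6.99 without the family and 7.23 to 18.3 with 1 library left out. Without the family and 1 library it was 3.85 to 10.2, and fell short of the threshold without KO library 2 (4.77), WT library 2 (6.51) or WT library 4 (3.85; p = 0.102 to 0.198, Fisher's exact test), where 1 or 2 such genes changed. By camera's direction, the skeletal muscle list reversed without KO library 1 (shift of skeletal muscle list -1.91 to 1.05 with 1 library left out) and the cell cycle list without KO library 3 (shift of cell cycle list -0.163 to 0.0208). Where the construction of an alternative does not show the cause, the cause was not tested.

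Of 128 named genes, 30 changed. Over 540 alternative values of these, 0 changed sign and 199 were no longer past the threshold. Over all named genes 42 of 2295 values changed sign, and 9 values could not be had. Over all lists 12 of 368 values changed direction, and of 252 alternatives of the 21 lists past the threshold 66 fell short of it.

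Nothing in the labels says that the sample numbers pair the libraries. Correlations of same-numbered libraries were 0.106, -0.03 and -0.27, and KO library 1 went best with WT library 3 (0.255). These were taken after centring within each group and are too few to exclude a pairing. With the replicate block, which leaves out WT library 4, 21 genes changed (20 higher, 1 lower), 14 of them among the 92, the Aim2 log2 fold change was -2.97 (adjusted p = 0.0605), 19 lists passed and the odds ratio near Aim2 was 8.84 (95% interval 0.991 to 37.1). Plin1 and Lep had too few reads to pass the filter and were not tested.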

Other observations

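The tests of reads shared within the IFI200 family, of wild-type RNA in KO library 1, of cell type shares, and of other splits for the interferon-stimulated list were chosen only after the result was seen. The genes of the next 2 paragraphs were named after their values were seen.

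Of the 92 changed genes, many stand on none of the fixed lists. Rnf213, a large ubiquitin ligase, rose 1.75-fold from 89.3 ± 3.07 CPM in WT to 157 ± 14.2 CPM in KO, and the helicase Ddx60 rose 2.31-fold. The GTPase genes Iigp1, Irgm1, Irgm2 and Igtp rose with log2 fold changes of 0.99, 0.75, 0.75 and 0.64, and reads of Irgm2 and Igtp, whose annotated positions overlap, are uncertain. The Schlafen genes Slfn9, Slfn4 and Slfn1 rose by 0.79, 0.97 and 0.63. Adar, which edits double-stranded RNA, Eif2ak2, the kinase activated by double-stranded RNA, and Irf9 rose by 0.58, 0.78 and 0.63. Among the genes that fell were S1pr1 (-0.59), Ltb (-0.64) and Siglecg (-0.70), which are expressed by lymphocytes, and Trem2 (-1.08) and Fabp5 (-0.88), which are expressed by macrophages. Rnf213, Ddx60 and Slfn9 passed in all 7 fits with a library left out, and the others named here in 0 to 4.

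Immunoglobulin genes were not a fixed list. Of 158 tested variable segments 135 had a log2 fold change above 0, with a median of 1.49, and 8 rose while 0 fell. The immunoglobulin genes together made up 10840, 17340 and 15290 CPM in KO and 3420, 6452, 8866 and 6901 CPM in WT. Igkc was at 2234 to 3485 CPM in KO and 708 to 1812 CPM in WT without passing. Ighg1 was at 76.6, 2633 and 732 CPM in the KO libraries, so that its level was set mainly by KO library 2. Ighd, the constant region of the IgD of naive B cells, was at 19.8 to 45.5 CPM in KO and 55.7 to 97.1 CPM in WT. Gm10705, a predicted gene on chromosome 3, had 73 reads over the KO libraries and 0 over the WT libraries, at least 30.6-fold higher in KO against a floor of 3 counts over the group.

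Of the 35 splits of the 7 libraries into 3 and 4, only 1, the real one, gave as many changed genes (92, highest other 2). This argues against chance for that count without excluding it, since 1 of 35 is the smallest share these splits can give. The other splits also mix KO and WT libraries within a group. The number of lists past camera gives no argument against chance, since 3 splits gave as many (real 21, highest other 23).

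The concentration of changed genes near Aim2 could come from sequence of a donor strain that stayed linked to the targeted gene. Such sequence predicts changed genes around Aim2, and the odds ratio within 10 Mb was 12.2. Ifi202b is known to be nearly silent in C57BL/6 mice and expressed in some other inbred strains, but the strains are not in the labels, so this stays a hypothesis. Reads shared between family members are argued against as the whole cause by the odds ratio of 6.99 without the family (95% interval 2.45 to 16.3), which rests on 6 genes. With a library left out as well, the interval reached under 1 without KO library 2 (odds ratio 4.77), WT library 2 (6.51) or WT library 4 (3.85), where 1 or 2 such genes changed. The splits do not test the concentration, since the others called at most 2 genes in all (real 11 near Aim2, highest other 0, 1 split as large). An effect of Aim2 loss itself on its neighbours stays open, since no test here separates it from linked sequence.

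The Aim2 reads in KO library 1 could reflect wild-type RNA or a heterozygous animal. Beyond the mean of KO libraries 2 and 3 they made up 19.3% of the WT level, with a lower bound of 12.8%. Ifi213 and Mid1, low in the other KO libraries, would then have needed 176 reads together in library 1, where 112 were found, against 126 at the level of KO libraries 2 and 3. Both were picked among genes called lower over all 7 libraries, KO library 1 included. A low level in that library was thus partly required by the choice, so the sum is not an independent test. The upper bound was 135 with counting error alone, which leaves out differences between animals. It was 440 with the spread of this sum between the WT libraries too, so the sum leaves the explanation open. Mid1 had 103 reads in KO library 1 against 118 and 127 in KO libraries 2 and 3. Ifi213 had 9 against 5 and 4, with 103 to 160 in the WT libraries. Mid1 lies on chromosome X and held most of the 112 reads. Heterozygosity at Aim2 need not change it, so the sum does not decide that case. Ifi213 and Ifi202b start 0.215 and 0.612 Mb from Aim2. Ifi202b was at 23.7 CPM in KO library 1, 21.3 and 29.95 CPM in KO libraries 2 and 3, and at most 0.107 CPM in WT. Both genes thus stood near the KO level in KO library 1. If their levels follow linked sequence, this argues against a WT copy of that stretch in KO library 1. That condition was not tested. Residual transcription from the targeted allele that differs between mice, and the assignment of reads by Salmon, were not tested.

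Higher interferon-stimulated genes in KO may reflect a response that follows the genotype. A larger share of a cell type among the 17 with a tested list may set that list apart as well. For 16 of them the largest gap with KO above WT was 0.14 on the log2 scale (endothelial). It was 0.681 for the interferon-stimulated list, with a WT SD of 0.168. A list that varies widely between libraries could shift without such a gap, and cell types without a list were not covered. The B lineage list stood apart in the other direction, by 0.30. The list outside these 16, of eosinophils, basophils and mast cells, had a KO mean of 1.03 above WT, against 0.979 for the interferon-stimulated list. WT library 4 (0.889) lay above KO libraries 1 and 3 (0.716 and 0.844) on that list. On the interferon-stimulated list WT library 4 was at 0.234, against 1.09 and 0.915 in those KO libraries. Over the WT libraries the first list ran from -1.16 to 0.889 and the second only from -0.12 to 0.234. By the rule written for this list the result was undecided, since its KO mean was not below that of the interferon-stimulated list. The comparison over the WT libraries was made beyond that rule and rests mainly on WT libraries 1 and 4. Within that limit, it argues against a larger share of those cells as the whole cause. Only 1 of the 35 splits, the real one, gave as large a difference of the list median (0.954, highest other 0.757), but 35 splits are too few for a list picked from 31 after the result was seen. A state of activation within a cell type, housing or infection, the expression of Ifi202b and linked donor sequence stay open and were not tested. So does the loss of Aim2, the biological difference that the design names.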
